A study of Mus musculus with 30 samples.

How the data were processed

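Messenger RNA was sequenced from lungs and tracheas of mouse embryos labelled as carrying a conditional deletion of Myocd and of their controls. Per the labels, each library came from a single lung or trachea: 10 lungs at E13.5 (right and left lobes), 10 lungs at E18.5 (right lobes) and 10 tracheas at E18.5. Per the labels' protocols, tissue was stored in TRIzol, RNA was cleaned with the RNeasy Micro Kit, and libraries were made with the Illumina TruSeq RNA Library Prep Kit V2, which does not mark strand. They were sequenced as single reads of 75 bases on a HiSeq4000. Mutants were labelled with 2 floxed Myocd alleles, a reverse tetracycline transactivator at Tbx4 and a tetracycline-dependent Cre. Controls were labelled with 1 floxed allele and the same transgenes, apart from E13.5 control replicate 1, labelled with 2 floxed alleles and no transgenes.

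The authors aligned reads to GRCm38 with STAR, per the submitters' processing notes; the STAR version is not given in the sources used here. The deposited tables hold raw counts of reads per gene, made with featureCounts 1.6.2 at its default options and the GENCODE vM17 annotation, per the file headers. At those options reads with several mapping places, and reads that overlap 2 genes, are not counted, and strand is ignored. Genes with near-identical copies, overlapping genes and antisense partners are therefore uncertain. Each of the 3 tables holds 53715 genes; 53620 of the gene IDs had a symbol in the reference annotation, GENCODE vM21, and 52056 had the same start and end there. Columns were assigned to labelled samples by their genotype letter and replicate number. Per the series design, the authors tested differential expression with DESeq2.

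From these counts, each tissue and stage was tested on its own, mutant against control, with edgeR 4.0.16 in R 4.3.3: TMM normalization, genes kept by filterByExpr, a robust quasi-likelihood fit and its F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. Levels are counts per M (CPM) on TMM-scaled library sizes, as mean and standard deviation (SD). Differences of the mutant effect between E18.5 trachea and lung, and between E18.5 and E13.5 lung, were tested as interaction contrasts on 20 libraries each. No covariate entered these fits. Total counts per library ran from 17.4 to 28.5 M in E13.5 lung, from 19.9 to 32.8 M in E18.5 lung and from 11.7 to 30.5 M in E18.5 trachea. The biological coefficient of variation was 0.140 in E13.5 lung, 0.184 in E18.5 lung and 0.370 in E18.5 trachea. No 2 libraries of a group were copies of each other: the lowest chi-square per degree of freedom among pairs was 4.11.

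The tests, the 25 gene lists (456 entries), the rule for named genes and the first set of alternatives were fixed before the data were examined. The lists covered contractile smooth muscle; SRF cofactors and targets; airway smooth muscle and peribronchial mesenchyme; vascular smooth muscle and pericyte; cardiac and skeletal muscle; cartilage; perichondrium, tendon and dense connective tissue; elastic matrix; branching signals; and stretch and YAP targets. They also covered alveolar type 1, alveolar type 2, airway secretory, ciliated and basal epithelium, neuroendocrine and neural cells, endothelium, erythroid cells, leukocytes, mesothelium, the oesophagus, thyroid and thymus, the cell cycle, the immediate early response, and hypoxia and glycolysis. Each list was tested against the other genes with camera of limma 3.58.1, at a preset correlation of 0.01 and adjusted over the 25 lists of a comparison. An estimated correlation and fry were alternatives. Several lists given below only with the estimated correlation passed at the preset correlation.

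Named genes were Myocd, the 8 largest rises and the 8 largest falls past the threshold with a mean of at least 5 CPM in the higher group and no overlap between genotypes, and up to 4 members of each list past the threshold. Where fewer than 2 members passed, the 2 most abundant were named by value. Predicted gene models were left out of the largest changes: 1 in E13.5 lung, 3 in E18.5 lung and 2 in the trachea. For the difference tests, the 5 largest differences at 5 CPM or more were named. A gene that the rule named in E13.5 lung is not reported here.

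The procedure was tested on simulated counts with known changes in 200 genes. In E13.5 lung (16324 genes) edgeR recovered 61.2% of 1.5-fold, 89.6% of 2-fold and 98.5% of 4-fold changes, with 7 false calls among 173. In E18.5 lung (17043 genes) it recovered 53.7%, 91.0% and 95.5%, with 10 false among 170. In the trachea (17731 genes) it recovered 13.4%, 59.7% and 80.3%, with 3 false among 105. For the tissue difference (19307 genes) it recovered 5.97%, 49.3% and 80.3%, with 7 false among 97; for the stage difference (18139 genes) 28.4%, 58.2% and 93.9%, with 3 false among 123. DESeq2 1.42.0 made 14.4% false calls in E13.5 lung, 14.4% in E18.5 lung, 16.4% in trachea, 23.5% for the tissue difference and 12.5% for the stage difference. A list lowered 1.5-fold was called in each of the 5 simulated tests, and 0 of 24 other lists were called by camera at either correlation or by fry. Simulated genes were drawn independently of each other. False list calls that come from correlated genes could therefore not show in this test.

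Replicate numbers recur between genotypes, and the labels do not say what a shared number means. In E18.5 lung, control and mutant libraries of the same number deviated together, with correlations of 0.141 to 0.346 in 4 of 4 pairs; by the preset limit of 0.1 these numbers pair the libraries. Without genes of the sex chromosomes, 2 of the 4 pairs passed that limit. A fit with the replicate number as a block is given with a named gene or list of E18.5 lung where it changed the call.

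Alternatives were DESeq2, limma-voom, RLE size factors, no filter, a replicate block, the Xist level as a covariate, a test against 1.2-fold, 1 fit of all 30 libraries, and leaving out each library in turn. Added after the data were seen were covariates for ribosomal RNA and for each library's slope of expression on transcript length, and fits without libraries that stood apart. Sequence similarity was searched with blastn 2.17.0, and plots were drawn with matplotlib 3.10.9. Deleted exons of Myocd are not stated in the labels, so the gene-level counts were not used to check the deletion.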

Results

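The series asked what differentiated airway smooth muscle contributes to airway size, to the cartilage of the trachea and to branching of the lung epithelium, by deleting Myocd. Myocd codes for myocardin, a coactivator of the transcription factor SRF that switches on contractile genes. RNA-seq counts were compared between mutant and control embryos in E13.5 lung (5 controls, 5 mutants), E18.5 lung (4 controls, 6 mutants) and E18.5 trachea (4 controls, 6 mutants). Intervals below are standard deviations between libraries (SD) or standard errors of a fit (SE).

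Myocd itself (chromosome 11, 65176561 to 65269989, GRCm38) kept reads in every library. Its level in E13.5 lung was 13.1 ± 4.05 CPM (SD, n = 5) in controls and 10.6 ± 3.26 CPM (SD, n = 5) in mutants, with single libraries at 10.1 to 18.8 CPM and at 6.73 to 13.2 CPM. In E18.5 lung it was 9.44 ± 2.57 CPM (SD, n = 4) in controls (6.14 to 12.1 CPM) and 7.4 ± 1.93 CPM (SD, n = 6) in mutants (5.69 to 10.4 CPM). In the trachea it was 4.58 ± 2.8 CPM (SD, n = 4) in controls (0.881 to 7.7 CPM) and 5.53 ± 1.98 CPM (SD, n = 6) in mutants (2.65 to 8.73 CPM). By edgeR the log2 fold changes were -0.29 (SE 0.24, adjusted p 0.998), -0.35 (SE 0.209, adjusted p 0.651) and 0.26 (SE 0.455, adjusted p 0.911), so none passed the test. Reads from exons outside the deleted part count for the gene, and the labels do not name the deleted exons, so these values do not check the genotype labels.

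At E13.5, genes of the contractile apparatus were lower in mutant lungs. Cnn1, which codes for calponin, fell 4.04-fold, from 29.3 ± 4.02 CPM (SD, n = 5) to 7.24 ± 4.04 CPM (SD, n = 5). Myh11 (chromosome 16, 14194535 to 14291372), the smooth muscle myosin heavy chain, fell 3.21-fold, from 157 ± 31 to 48.9 ± 25.5 CPM. Synpo2 (chromosome 3, 123076519 to 123236149), an actin-bundling protein of muscle, fell 2.78-fold, from 40.6 ± 1.84 to 14.6 ± 3.29 CPM. Acta2, smooth muscle actin, fell 2.29-fold, from 333 ± 30.8 to 145 ± 32.8 CPM, and Lmod1, which nucleates actin filaments, fell 2.87-fold, from 7.5 ± 1.16 to 2.61 ± 0.849 CPM.

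By edgeR's quasi-likelihood test, the log2 fold changes in E13.5 lung were -2.01 (SE 0.275, adjusted p 0.00938) for Cnn1, -1.68 (SE 0.269, adjusted p 0.0252) for Myh11 and -1.47 (SE 0.127, adjusted p 0.00111) for Synpo2. They were -1.2 (SE 0.147, adjusted p 0.0065) for Acta2 and -1.52 (SE 0.199, adjusted p 0.00863) for Lmod1. Of the 28 measured contractile genes, 6 fell, or 10 adjusted over the list alone, and 0 rose. The list's median log2 fold change was -0.29, and the list fell against other genes (camera adjusted p 1.17e-44; adjusted p = 0.0134 with an estimated correlation). A median at least as far from 0 came from 6 of 100 splits of these libraries, the real one included, so chance was not excluded for the median. The list's score per library, a mean of log2 levels, was 0.0586 to 0.418 in controls and -0.474 to 0.0321 in mutants. These ranges did not overlap, though the highest mutant, replicate 5, lay near the lowest control, replicate 2. The list of airway smooth muscle and peribronchial mesenchyme fell as well, with a median of -0.09 and 1 of 15 members past the edgeR test, 2 adjusted over the list alone (adjusted p = 0.0214 with an estimated correlation). Its member Lgr6, an R-spondin receptor found on airway smooth muscle progenitors, had a log2 fold change of -0.75 (SE 0.112, adjusted p 0.0152), from 26.9 ± 3.03 to 15.9 ± 2.33 CPM. Of 14 SRF cofactors and targets, 1 fell over all genes and 1 adjusted over the list alone: Tgfb1i1, a focal adhesion adaptor, at 92.5 ± 6.03 against 66.5 ± 7.02 CPM. The SRF list had a median of -0.1, with camera adjusted p 2.56e-05 at the preset correlation and 0.133 with an estimated correlation. Cytoskeletal actin Actb was 3055 ± 257 against 2854 ± 244 CPM and did not pass the test. Vascular smooth muscle and pericyte genes had a median of -0.01, with 0 of 15 past the edgeR test over all genes or over the list alone.

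Other falls at E13.5 included Fhdc1, a formin-family protein that acts on actin and microtubules, at 42.1 ± 1.83 against 16.5 ± 4.67 CPM. Crispld2, a secreted protein of lung mesenchyme, was 22.7 ± 1.02 against 10.8 ± 2.84 CPM, and Psd, an activator of the small GTPase ARF6, was 13.7 ± 2.52 against 5.97 ± 1.39 CPM. Their edgeR log2 fold changes were -1.34 (SE 0.164, adjusted p 0.0065), -1.06 (SE 0.151, adjusted p 0.0128) and -1.19 (SE 0.166, adjusted p 0.0108). Genes that rose were Psph, an enzyme of serine synthesis, by 0.56 (SE 0.0732, adjusted p 0.00863), Mns1 by 0.62 (SE 0.0731, adjusted p 0.0065) and Rpl29 by 1.08 (SE 0.143, adjusted p 0.00863), all by edgeR. Mns1, a protein of the ciliary axoneme, is uncertain because 53.0% of its exon bases overlap a gene on the other strand. Rpl29, a ribosomal protein gene, is uncertain because it has many processed copies. The list of branching signals had a median of -0.07 (0 of 26 past the edgeR test, 1 fell adjusted over the list alone). Its camera adjusted p was 0.00349 at the preset correlation and 0.205 with an estimated correlation. Stretch and YAP targets had a median of -0.05, with 0 of 13 past the edgeR test by either adjustment. Ptch1, the hedgehog receptor, was 341 ± 15.9 against 357 ± 19.9 CPM, and Etv5, a target of FGF signalling, 299 ± 28.5 against 288 ± 46.7 CPM.

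At E13.5, ciliated, basal and secretory epithelium had medians of -0.08, -0.18 and -0.49, with 0 of 9, 0 of 8 and 0 of 4 past the edgeR test and 2 secretory falls adjusted over the list alone. The secretory list had adjusted p = 0.0614 with an estimated correlation, and the basal list adjusted p = 0.0609 with an estimated correlation. Alveolar type 1 and type 2 lists had medians of -0.04 (adjusted p = 0.365 with an estimated correlation) and -0.08 (adjusted p = 0.313 with an estimated correlation). The type 1 median was 0.0056 without control replicate 1 and 0.0186 without mutant replicate 3, and the type 2 median 0.0035 without control replicates 1 and 4. Cartilage genes had a median of 0.08 (0 of 18 past the edgeR test, 3 rose adjusted over the list alone; adjusted p = 0.0609 with an estimated correlation), and Col2a1, the main collagen of cartilage, was 108 ± 11 against 106 ± 13.6 CPM. Perichondrium and elastic matrix had medians of -0.01 and -0.06 and did not pass camera.

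In all, 34 genes passed the edgeR test in E13.5 lung, 3 higher and 31 lower in mutants, of 16486 tested. The count was 19, 20, 19 and 17 without control replicate 1, 3, 4 or 5, 20 without mutant replicate 3 and 56 without mutant replicate 1. The 56 were 17 higher and 39 lower, the 29 without mutant replicate 4 were 10 and 19, and the 82 of DESeq2 were 23 and 59. The count was 2 without control replicates 1 and 4 together, a choice made after seeing the data. The call of Cnn1 was lost without mutant replicate 1 (-1.99), and that of Crispld2 without control replicate 5 (-1.05). Myh11 lost its call without control replicate 1, 3, 4 or 5 or mutant replicate 1, 2, 3 or 4 (-1.71 to -1.56). Lgr6 lost its call without control replicate 1, 3, 4 or 5 or mutant replicate 2 or 3 (-0.75 to -0.69), and Tgfb1i1 without control replicate 1, 3, 4 or 5 or mutant replicate 2, 3 or 4 (-0.51 to -0.44).

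**Figure D1:**
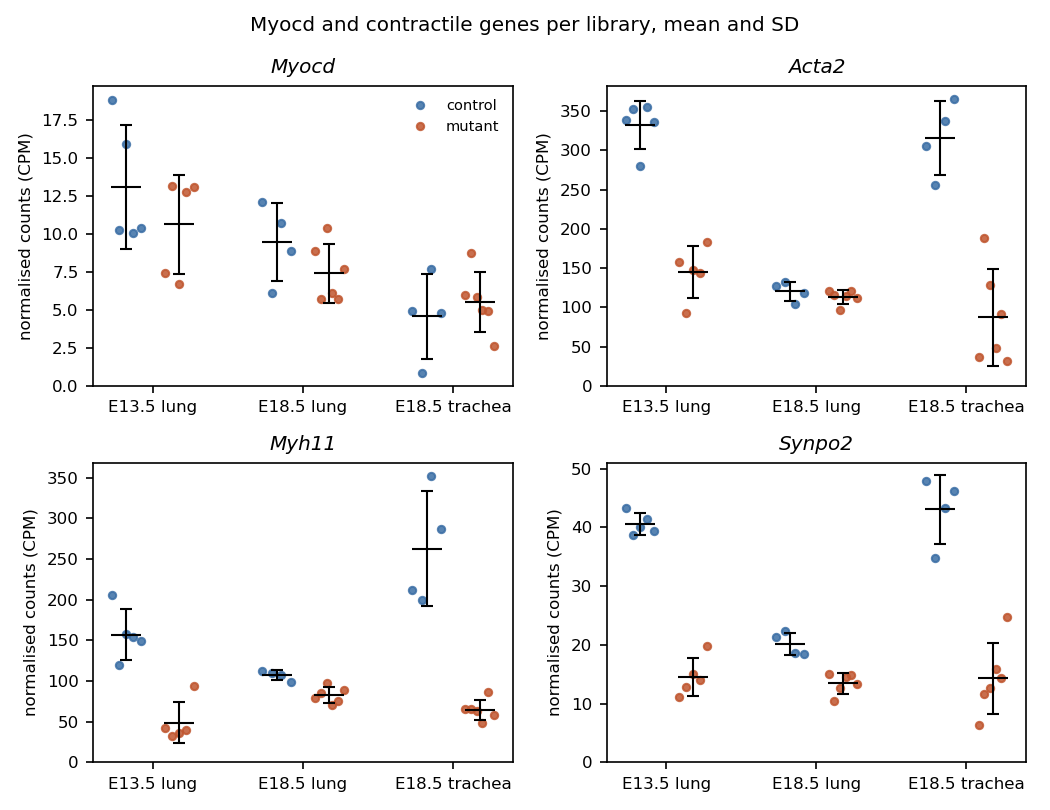
Level in CPM of Myocd, Acta2, Myh11 and Synpo2 in each control and mutant library of E13.5 lung, E18.5 lung and E18.5 trachea, with the group mean and SD. Myh11 was 157 ± 31 against 48.9 ± 25.5 CPM in E13.5 lung, 107 ± 6.06 against 83 ± 9.7 CPM in E18.5 lung and 263 ± 71 against 64.6 ± 12.4 CPM in the trachea, while Myocd overlapped between genotypes in each.

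At E18.5, mutant lungs had lower levels of genes of ciliated and secretory airway epithelium. Scgb1a1, the secretoglobin of club cells, fell 1.87-fold, from 698 ± 51.2 CPM (SD, n = 4) to 373 ± 52 CPM (SD, n = 6). Foxj1, the transcription factor that drives motile ciliogenesis, fell from 61.7 ± 6.12 to 41.1 ± 5.27 CPM. Dnah5, an outer dynein arm heavy chain, fell 1.77-fold, from 18.6 ± 2.62 to 10.5 ± 2.2 CPM, and Rsph4a, a radial spoke head protein, fell 1.72-fold, from 20.1 ± 1.76 to 11.7 ± 1.86 CPM. Of the contractile genes, Myh11 fell from 107 ± 6.06 to 83 ± 9.7 CPM and Synpo2 from 20.2 ± 1.93 to 13.49 ± 1.77 CPM.

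By edgeR, 8 of 18 ciliated genes fell in E18.5 lung, or 16 adjusted over the list alone, with a median log2 fold change of -0.69 and adjusted p = 0.0106 with an estimated correlation. The fits gave -0.59 (SE 0.0962, adjusted p 0.00876) for Foxj1, -0.82 (SE 0.15, adjusted p 0.0139) for Dnah5, -0.78 (SE 0.126, adjusted p 0.00764) for Rsph4a and -1.21 (SE 0.209, adjusted p 0.00994) for Fam183b, a protein of the ciliary axoneme. Outside the list, Dnah3, an inner arm dynein, had -1.08 (SE 0.154, adjusted p 0.00326), from 21.2 ± 3.83 to 10 ± 2.03 CPM. Cfap46, of the ciliary central pair, had -1.11 (SE 0.185, adjusted p 0.00994), from 18.2 ± 4.05 to 8.44 ± 2.14 CPM. Ccdc162, Lrrc36 and Fam216b, whose roles are less known, had -1.05 (SE 0.158, adjusted p 0.00421), -1.1 (SE 0.213, adjusted p 0.0192) and -1.21 (SE 0.219, adjusted p 0.0139); with the replicate block Lrrc36 (-0.93) and Fam216b (-1.09) did not pass. The cadherin gene Dchs2 had -1.26 (SE 0.263, adjusted p 0.0327), not passing with the block (-1.02), and Aldh3a1, an aldehyde dehydrogenase, -1.94 (SE 0.401, adjusted p 0.0433), from 6.78 ± 1.89 to 1.78 ± 1.16 CPM. Of 12 secretory genes 4 fell, or 8 adjusted over the list alone, with a median of -0.48 and adjusted p = 0.0137 with an estimated correlation. They were Scgb1a1 at -0.9 (SE 0.0914, adjusted p 0.000226), the cytochromes P450 Cyp2s1 at -0.53 (SE 0.0782, adjusted p 0.00396) and Cyp2f2 at -0.43 (SE 0.0857, adjusted p 0.0256), and the retinaldehyde dehydrogenase gene Aldh1a1 at -0.55 (SE 0.0997, adjusted p 0.0146); with the block Cyp2f2 (-0.39) and Aldh1a1 (-0.51) did not pass. Basal epithelium had a median of 0.07, with 0 of 9 past the test by either adjustment.

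Of 29 contractile genes, 3 fell in E18.5 lung, or 6 adjusted over the list alone, with a list median of -0.12 (camera adjusted p 0.00011; adjusted p = 0.0137 with an estimated correlation). The median was -0.0706 without control replicate 1, -0.0776 with the length slope as a covariate and -0.0475 with ribosomal RNA as a covariate, where the list no longer passed (adjusted p 0.0537); both covariates were chosen after seeing the data. They were Synpo2 at -0.58 (SE 0.118, adjusted p 0.0268), the laminin receptor subunit Itga7 at -0.46 (SE 0.094, adjusted p 0.0268) and Myh11 at -0.37 (SE 0.0804, adjusted p 0.0426) by edgeR; with the replicate block Synpo2 (-0.62) did not pass. The SRF list, the list of airway smooth muscle and peribronchial mesenchyme and the vascular smooth muscle list had medians of -0.02, -0.04 and 0.03, and none passed, with 0, 1 and 0 falls adjusted over the list alone; the SRF mean and test had the opposite sign to its median. Genes of perichondrium, tendon and dense connective tissue had a median of 0.19 with adjusted p = 0.049 with an estimated correlation; 0 of 15 passed by edgeR over all genes and 3 rose adjusted over the list alone. Its members Col1a2 and Col3a1, fibrillar collagens, were 1596 ± 222 against 1823 ± 74 CPM and 2557 ± 248 against 2707 ± 50 CPM. Elastic matrix genes had a median of 0.14 (0 of 16 past the edgeR test, 1 rose adjusted over the list alone; adjusted p = 0.207 with an estimated correlation).

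All 17 of 17 alveolar type 2 genes had a log2 fold change below 0 in E18.5 lung, with a median of -0.13 (camera adjusted p 5.22e-05; adjusted p = 0.392 with an estimated correlation). Sftpd, surfactant protein D, fell from 226 ± 20.8 to 171 ± 19.5 CPM, a log2 fold change of -0.41 (SE 0.083, adjusted p 0.0268) by edgeR. It was the 1 of 17 type 2 genes past the test (3 adjusted over the list alone). Sftpc, surfactant protein C, was 9520 ± 656 against 9426 ± 1054 CPM, and the type 1 gene Ager was 1725 ± 70.7 against 1738 ± 149 CPM. The type 1 list had a median of -0.03 with 0 of 16 past the edgeR test. The growth factor receptor Fgfr2 was 340 ± 25.2 against 344 ± 44.3 CPM, among 26 branching genes with a median of 0.02 and 0 past the edgeR test. Crim1, a membrane protein that binds BMPs, had -0.42 (SE 0.073, adjusted p 0.00994) and was the 1 of 14 stretch and YAP targets past the edgeR test. Rises were led by Pianp at 1.07 (SE 0.158, adjusted p 0.00411), from 9.01 ± 2.46 to 19 ± 2.4 CPM, and by the metalloproteinase gene Mmp23 at 0.86 (SE 0.165, adjusted p 0.0184). The BMP family gene Gdf10 rose by 0.56 (SE 0.118, adjusted p 0.0322), not passing with the block (0.59), the RNA-binding protein gene Mex3a by 0.44 (SE 0.0911, adjusted p 0.0322) and the actin-binding protein gene Marcksl1 by 0.36 (SE 0.0759, adjusted p 0.0371).

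In all, 102 genes passed the edgeR test in E18.5 lung, 6 higher and 96 lower, of 17467 tested. Ribosomal RNA genes took 0.0924% to 0.120% of counts in controls and 0.123% to 0.169% in mutants (exact permutation p 0.00476, 0.0714 adjusted over 15 tests). With 23622 ± 638 genes in controls and 21375 ± 931 in mutants, fewer genes were detected in mutants (exact permutation p 0.0143, adjusted 0.107). Olfactory receptor genes, a measure of background, summed to 24.9 ± 2.28 CPM in controls and 19.1 ± 4.02 CPM in mutants (exact permutation p 0.0429, adjusted 0.214). With ribosomal RNA as a covariate, chosen after seeing the data, 5 genes passed, 4 of them among the 102, and the medians were -0.51 for ciliated, -0.37 for secretory and -0.05 for contractile genes. With transcript length slope, likewise chosen, 54 genes passed. The count was 26, 205, 48 and 43 without control replicate 1, 2, 3 or 4 and 59 without mutant replicate 4. The 205 were 78 higher and 127 lower, and the 264 of DESeq2 were 47 and 217, so the small share of rises depended on control replicate 2 and on the tool. With the replicate block, 73 genes passed, 52 of them among the 102. The adjusted p of the 7 named genes that did not pass with it was 0.0751 to 0.125. With it, the cartilage, leukocyte and mesothelium lists passed camera at the preset correlation (medians 0.14, -0.05 and -0.16, adjusted p 0.0310, 0.0327 and 0.0320). Without the block, their camera adjusted p with an estimated correlation was 0.463, 0.463 and 0.622.

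Among the genes above, Scgb1a1, Foxj1, Rsph4a, Dnah3, Ccdc162, Cyp2s1 and Pianp passed in E18.5 lung with any 1 library left out. The calls of Fam183b (-1.09), Cfap46 (-1.03) and Crim1 (-0.36) were lost without control replicate 1, and those of Fam216b (-1.2 to -1.0), Dnah5 (-0.77 to -0.76) and Aldh1a1 (-0.56 to -0.48) without control replicate 1 or 3. Those of Mmp23 (0.81 to 0.92), Lrrc36 (-1.1 to -1.02) and Cyp2f2 (-0.43 to -0.38) were lost without control replicate 1, 3 or 4 or mutant replicate 4. Synpo2 lost its call without control replicate 1, 2, 3 or 4 or mutant replicate 4 or 6 (-0.63 to -0.53), and Itga7 without control replicate 1, 3 or 4 or mutant replicate 2, 4 or 6 (-0.5 to -0.39). Gdf10 (0.46 to 0.56) and Sftpd (-0.42 to -0.35) lost theirs without control replicate 1, 3 or 4 or mutant replicate 1, 4 or 6. Myh11 lost its call without control replicate 1, 2, 3 or 4 or mutant replicate 1, 2, 4, 5 or 6 (-0.41 to -0.33). Aldh3a1 lost its call without control replicate 1, 3 or 4 or mutant replicate 2, 3, 4 or 5 (-2.06 to -1.74), and Dchs2 without control replicate 1, 3 or 4 or mutant replicate 2, 4, 5 or 6 (-1.38 to -1.03). Mex3a lost its call without control replicate 1, 3 or 4 or mutant replicate 1, 2 or 6 (0.37 to 0.45), and Marcksl1 without control replicate 1, 3 or 4 or mutant replicate 2, 4, 5 or 6 (0.29 to 0.37).

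**Figure D2:**
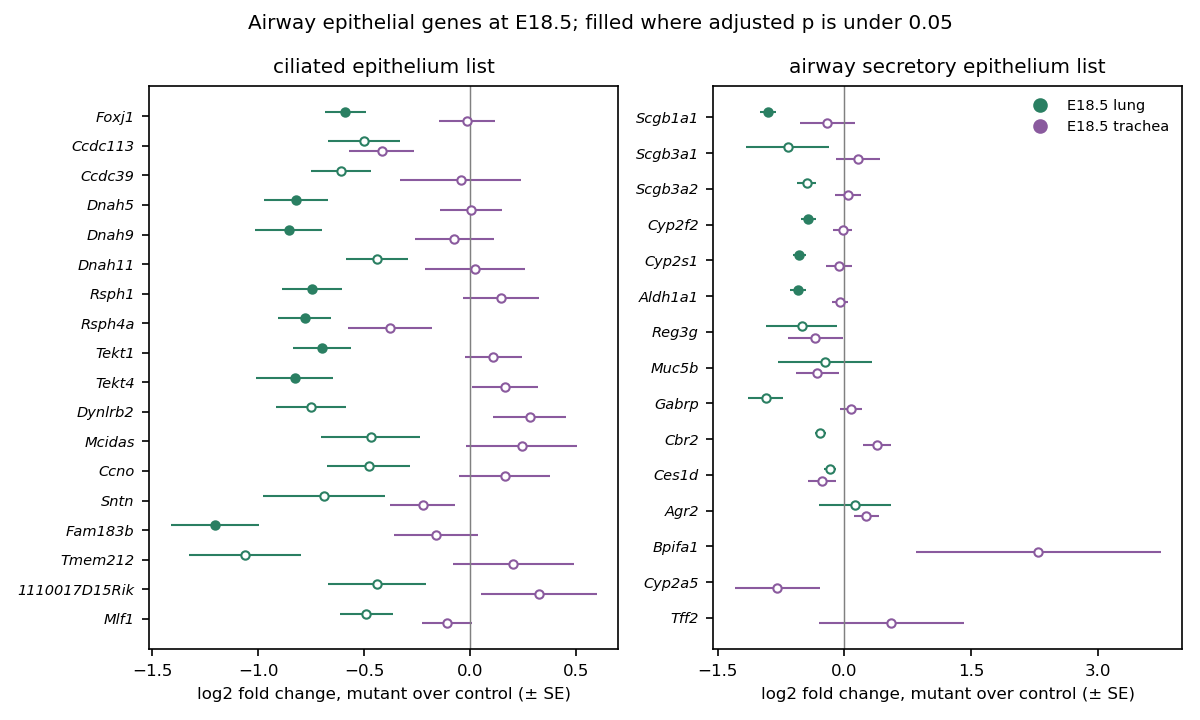
Log2 fold change, mutant over control, with its SE, of each member of the ciliated and secretory lists in E18.5 lung and E18.5 trachea; filled points have an edgeR adjusted p under 0.05. Ciliated genes had a median of -0.69 in the lung and 0.01 in the trachea, and secretory genes of -0.48 and -0.02.

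In the E18.5 trachea, genes that act in smooth muscle contraction were among those that fell. Chrm2, the M2 muscarinic acetylcholine receptor, fell 5.48-fold by the edgeR fit, with means of 31.1 ± 3.78 CPM (SD, n = 4) in controls and 5.59 ± 2.99 CPM (SD, n = 6) in mutants. Myh11 fell 4.06-fold, from 263 ± 71 to 64.6 ± 12.4 CPM, and Synpo2 fell 3.02-fold, from 43.1 ± 5.85 to 14.3 ± 6.06 CPM. Mylk, the kinase that activates smooth muscle myosin, fell from 211 ± 26.9 to 105 ± 16.8 CPM, and Rgs2, which limits signalling by Gq-coupled receptors, fell 2.3-fold, from 75.3 ± 11.7 to 32.6 ± 6.69 CPM. Cytl1, a secreted protein of cartilage, fell from 306 ± 29.6 to 146 ± 18.3 CPM.

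The edgeR log2 fold changes in the trachea were -2.46 (SE 0.383, adjusted p 0.0339) for Chrm2, -2.02 (SE 0.171, adjusted p 7.23e-05) for Myh11 and -1.59 (SE 0.262, adjusted p 0.038) for Synpo2. They were -1.0 (SE 0.13, adjusted p 0.00657) for Mylk, -1.2 (SE 0.157, adjusted p 0.00657) for Rgs2 and -1.07 (SE 0.109, adjusted p 0.000584) for Cytl1. Cpxm2, a carboxypeptidase-like protein, had -1.36 (SE 0.186, adjusted p 0.0102), from 74.5 ± 13.2 to 29 ± 7.59 CPM, and the monooxygenase-like gene Moxd1 -1.24 (SE 0.187, adjusted p 0.0233), from 76 ± 13.3 to 32.1 ± 8.83 CPM. Tymp, thymidine phosphorylase, had -1.04 (SE 0.176, adjusted p 0.0478) and is uncertain because 42.0% of its exon bases overlap another gene. Of 29 contractile genes, 3 fell, or 15 adjusted over the list alone, with a median of -0.64 (camera adjusted p 9.06e-32; adjusted p = 9.07e-05 with an estimated correlation). Acta2 was 316 ± 46.8 against 87.5 ± 61.7 CPM, a log2 fold change of -1.85 (SE 0.504, adjusted p 0.573), and did not pass by edgeR. The SRF list had a median of -0.18, with 0 of 14 past the edgeR test and 1 fall adjusted over the list alone (adjusted p = 0.301 with an estimated correlation). The list of airway smooth muscle and peribronchial mesenchyme had a median of -0.05, with 1 of 15 past the edgeR test and 2 adjusted over the list alone (adjusted p = 0.301 with an estimated correlation). That median turned to 0.128 with ribosomal RNA and 0.103 with length slope as a covariate, 0.0077, 0.0119 and 0.116 without control replicate 3 or 4 or mutant replicate 4, and 0.0619 without control replicate 2 and mutant replicate 4. Vascular smooth muscle and pericyte genes had a median of -0.07 and did not pass.

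Cartilage genes had a median log2 fold change of -0.75 in the trachea, with 23 of 25 below 0. The list's score was 0.06 to 0.70 in the controls and -0.94 to -0.39 in 4 mutants, but 0.35 and 0.37 in mutant replicates 5 and 6, inside the control range. Of the genes, 1 fell over all genes and 14 adjusted over the list alone. The list passed camera at the preset correlation (adjusted p 1.35e-23), but adjusted p = 0.186 with an estimated correlation. Col2a1 was 8728 ± 1749 against 4885 ± 2999 CPM, a log2 fold change of -0.84 (SE 0.404, adjusted p 0.733) by edgeR, and Col11a1, another cartilage collagen, was 1698 ± 467 against 916 ± 378 CPM. Perichondrium and dense connective tissue had a median of -0.12 (0 of 16 past the edgeR test; adjusted p = 0.429 with an estimated correlation), which turned to 0.0649 with ribosomal RNA and 0.0346 with length slope as a covariate. Stretch and YAP targets had a median of -0.29 (0 of 14; adjusted p = 0.301 with an estimated correlation), and branching signals of -0.11 (0 of 26; adjusted p = 0.344 with an estimated correlation). Elastic matrix genes had a median of -0.06 and did not pass; elastin, Eln, was 11731 ± 1263 against 8414 ± 1454 CPM. Airway epithelium had medians of 0.01 for ciliated, -0.02 for secretory and 0.01 for basal genes, with 0 of 18, 0 of 15 and 0 of 13 past the edgeR test, and Foxj1 was 218 ± 13.9 against 215 ± 42.2 CPM. The ciliated median was -0.17 without control replicate 2 and mutant replicate 4. The ciliated test had the opposite sign to its median, and the secretory mean the opposite sign to its median and test. Alveolar type 1 and type 2 lists had medians of -0.07 and 0.03 and did not pass; 1 type 1 gene fell and 1 type 2 gene rose adjusted over the list alone.

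In all, 13 genes passed the edgeR test in the trachea, 1 higher and 12 lower, of 18315 tested. Tracheal mutant replicate 4 had 15.7% of its counts in ribosomal RNA genes against 0.983% to 7.67% in other tracheal libraries. It and control replicate 2 had the lowest totals, 12.4 and 11.7 M counts. Without both, a choice made after seeing the data, 45 genes passed, 11 of them among the 13. With covariates likewise chosen, 3 genes passed for ribosomal RNA and 7 for transcript length slope; 156 passed in 1 fit of all 30 libraries, 41 higher and 115 lower, and 89 in DESeq2, 17 and 72. The count was 7, 6 and 3 without control replicate 1, 3 or 4, 8 without mutant replicate 1 and 5 without mutant replicate 3. Myh11 and Cytl1 passed with any 1 library left out; Rgs2 (-1.15) and Mylk (-0.97) did not without control replicate 4. Cpxm2 lost its call without control replicate 3 or 4 or mutant replicate 3 (-1.33 to -1.28), and Moxd1 without control replicate 2, 3 or 4 or mutant replicate 1, 2 or 3 (-1.23 to -1.16). Chrm2 lost its call without control replicate 1, 2, 3 or 4 or mutant replicate 1, 2, 3 or 5 (-2.57 to -2.39), Synpo2 without control replicate 1, 2, 3 or 4 or mutant replicate 2, 3, 4 or 5 (-1.69 to -1.54) and Tymp without control replicate 1, 3 or 4 or mutant replicate 1, 2, 3, 4 or 6 (-1.08 to -0.9).

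**Figure D3:**
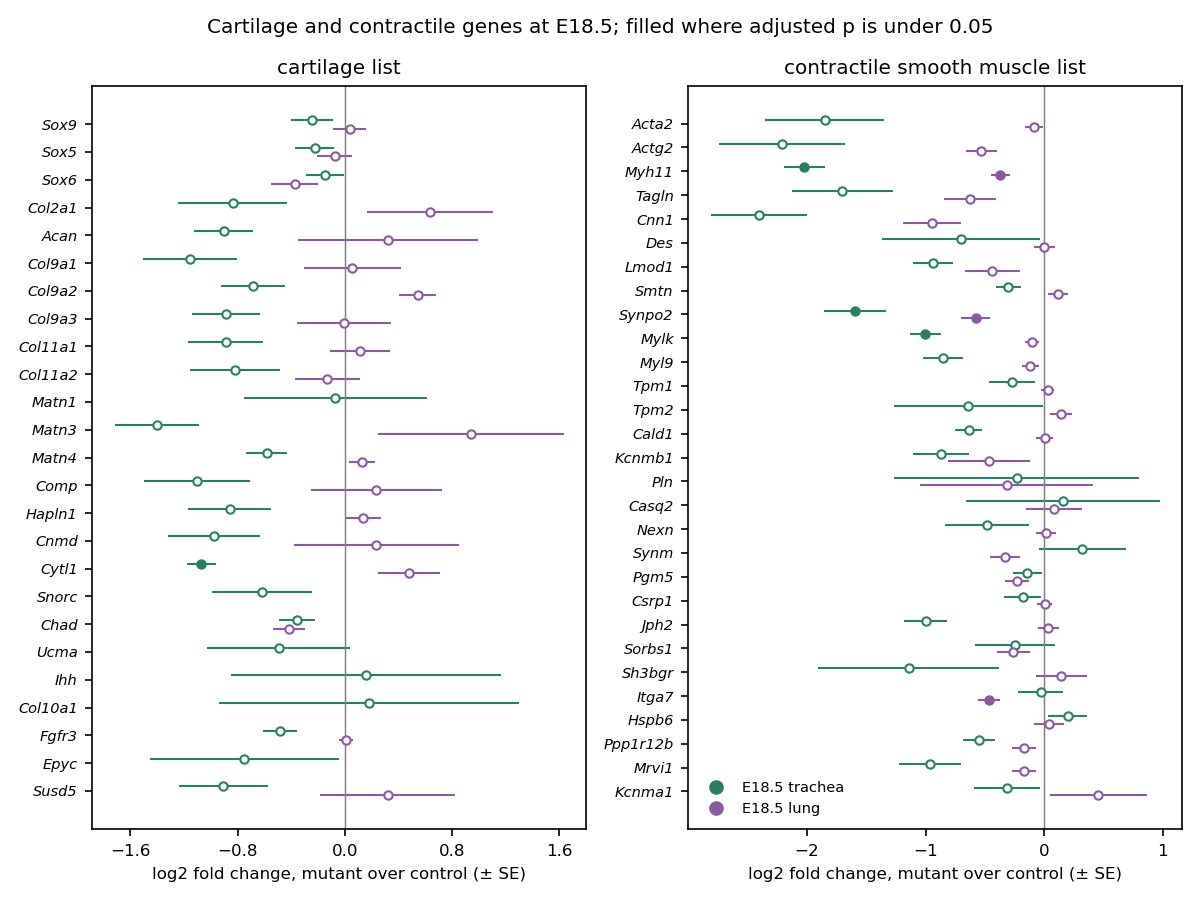
Log2 fold change, mutant over control, with its SE, of each member of the cartilage and contractile lists in E18.5 lung and E18.5 trachea; filled points have an edgeR adjusted p under 0.05. Cartilage genes had a median of -0.75 in the trachea and 0.13 in the lung, and contractile genes of -0.64 and -0.12.

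The mutant effect was compared between tissues at E18.5, as the effect in trachea minus the effect in lung. The fit treats the 20 libraries as independent; lung and trachea libraries of the same number deviated together, with correlations of 0.116 to 0.224 in controls (4 of 4 over 0.1) and 0.0694 to 0.291 in mutants (5 of 6). The contractile genes Myh11 and Mylk differed by -1.61 (SE 0.203, adjusted p 0.00035) and -0.86 (SE 0.151, adjusted p 0.0303) in edgeR; Mylk was 755 ± 54.1 against 683 ± 36.5 CPM in the lung and 220 ± 28.3 against 110 ± 17.7 CPM in the trachea. Rgs2, outside that list, differed by -1.07 (SE 0.178, adjusted p 0.0163). Cytl1 differed by -1.5 (SE 0.181, adjusted p 0.000323); it was at 2.46 ± 0.496 CPM in control lung and 319 ± 30.7 CPM in control trachea. Lrrc23, a radial spoke protein of cilia, differed by 1.2 (SE 0.195, adjusted p 0.0142), at 58.8 ± 9.16 against 34.9 ± 5.69 CPM in the lung and 219 ± 22.8 against 299 ± 59.5 CPM in the trachea; with letter and number as a block it did not pass (1.19, adjusted p 0.0662). These 5 genes were all that passed of 19859. The contractile list differed by a median of -0.6 (2 of 29 lower, 11 adjusted over the list alone; adjusted p = 5.21e-06 with an estimated correlation). The cartilage list differed by -0.96 (1 of 25, 5 adjusted over the list alone; adjusted p = 0.022 with an estimated correlation). In the trachea alone this list had adjusted p = 0.186 with an estimated correlation. Of its 19 genes measured in E18.5 lung, 4 were at 5 CPM or more in control lung and 10 times higher in control trachea. The lung side of the difference thus rests on few genes that mark cartilage. Ciliated genes differed by 0.78 (0 of 18, 10 higher adjusted over the list alone; adjusted p = 0.022 with an estimated correlation), and secretory genes by 0.54 (6 adjusted over the list alone; adjusted p = 0.172 with an estimated correlation).

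The count of 5 for the tissue difference was 12 without tracheal control replicate 2 and mutant replicate 4, a choice made after seeing the data. It was 9, 3 and 2 without lung control replicate 2, 3 or 4, 3 without tracheal control replicate 3 and 8 without tracheal mutant replicate 4. Lrrc23 lost its call without E18.5 lung control replicate 4 (1.11), and Rgs2 without E18.5 lung control replicate 3 or 4 or E18.5 trachea control replicate 3 or 4 (-1.05 to -1.0). Mylk lost its call without E18.5 lung control replicate 2, 3 or 4 or E18.5 lung mutant replicate 1, 3, 4, 5 or 6 or E18.5 trachea control replicate 3 or 4 or E18.5 trachea mutant replicate 6 (-0.87 to -0.78).

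The mutant effect was also compared between stages in the lung, as the effect at E18.5 minus the effect at E13.5. Acta2 differed by 1.11 (SE 0.173, adjusted p 0.00701) in edgeR: it was 334 ± 31.6 against 146 ± 33.6 CPM at E13.5 and 120 ± 12.4 against 113 ± 8.92 CPM at E18.5. Lgr6 differed by 1.26 (SE 0.228, adjusted p 0.0459), Mns1 by -1.27 (SE 0.15, adjusted p 0.000245) and Nupr1, a stress-responsive nuclear protein, by -1.47 (SE 0.227, adjusted p 0.00701). Nupr1 was at low levels at E13.5, 1.52 ± 0.363 against 3.19 ± 0.719 CPM, and 79.2 ± 9.23 against 59.6 ± 8.11 CPM at E18.5. Mns1 is uncertain here too, as 53.0% of its exon bases overlap a gene on the other strand. Ccdc150, below the level set for named genes and chosen after its values were seen, differed by -1.6 (SE 0.251, adjusted p 0.00701). These 5 genes were all that passed of 18639. With the replicate block 1 gene passed, Mns1 (-1.33, adjusted p 0.00929), and Acta2 (1.12, adjusted p 0.0840), Lgr6 (1.15, adjusted p 0.241), Nupr1 (-1.47, adjusted p 0.0547) and Ccdc150 did not. That block also used the E13.5 numbers, whose libraries did not deviate together (correlations of -0.377 to 0.0169). The contractile list differed by a median of 0.18, with 1 of 29 past the edgeR test and 8 adjusted over the list alone, and adjusted p = 0.121 with an estimated correlation. None of the 25 lists passed with an estimated correlation. At the preset correlation several did, among them the contractile (camera adjusted p 4.39e-11), cell cycle (4.39e-11) and cardiac (1.94e-05) lists. The count was 11 without E13.5 mutant replicate 1, 16 without E13.5 mutant replicate 5, 3 without E18.5 control replicate 1, 19 without E18.5 control replicate 2 and 8 without E18.5 mutant replicate 2. Lgr6 lost its call without E13.5 lung control replicate 1, 3, 4 or 5 or E13.5 lung mutant replicate 1, 2 or 3 or E18.5 lung control replicate 1, 3 or 4 or E18.5 lung mutant replicate 3, 4, 5 or 6 (1.17 to 1.25).

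Synpo2, Myh11 and the predicted gene Gm1821 were lower in mutants in all 3 comparisons, Mycl, a MYC family gene, in both lung stages, and Crispld2 in E13.5 lung and E18.5 trachea. With the replicate block, Synpo2 did not pass in E18.5 lung (-0.62). Mycl and Gm1821 were chosen here after the values were seen, for being shared. For E13.5 and E18.5 lung 4 genes were lower in both, against 0.128 expected of independent lists among 15623 genes. For E13.5 lung and trachea the overlap was 4 against 0.0211 of 15674, and for E18.5 lung and trachea 3 against 0.0698 of 16499. Lung and trachea of the same number at E18.5 may come from the same embryo, in which case the overlap between these tissues is not of independent samples. With lung from odd and trachea from even numbers, or the reverse, the overlap was 1 gene, Gm1821. Those fits called 2 and 4 genes in lung and 6 and 2 in trachea, too few to judge Synpo2 and Myh11.

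Gm1821, a transcribed processed pseudogene of ubiquitin (chromosome 14, 46084028 to 46085000), was singled out after its values were seen. In E18.5 lung it was 28.5 ± 2.47 against 0.961 ± 0.36 CPM, in trachea 34.6 ± 8.44 against 1.1 ± 0.334 CPM and in E13.5 lung 26 ± 14.3 against 0.86 ± 0.13 CPM. The edgeR log2 fold changes were -4.89 (SE 0.194, adjusted p 6.13e-11), -4.93 (SE 0.239, adjusted p 7.42e-08) and -4.91 (SE 0.757, adjusted p 0.0204). At E13.5, control replicate 4 was at 0.675 CPM, inside the mutant range of 0.645 to 0.965 CPM, and the other controls were at 30.3 to 34.0 CPM. The E13.5 call was lost without control replicate 1, 3 or 5 or mutant replicate 1, 2, 3, 4 or 5 (-4.96 to -4.81).

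**Figure D4:**
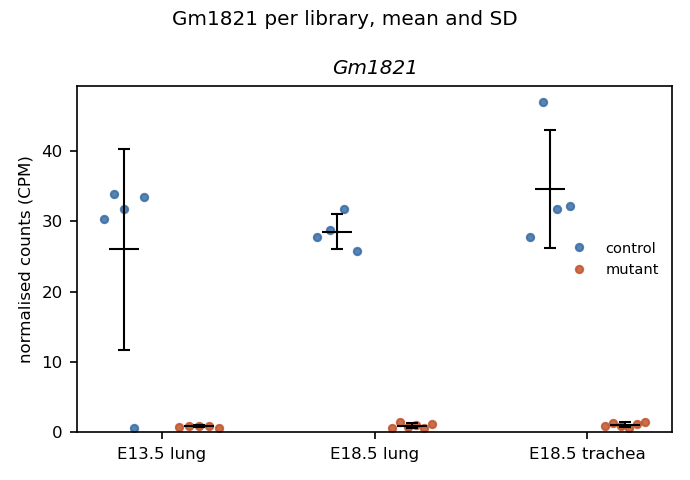
Level of Gm1821 in CPM in each control and mutant library of the 3 comparisons. E13.5 control replicate 4 lies at 0.675 CPM with the mutants, whose mean was 0.860 CPM, and the other E13.5 controls at 30.3 to 34.0 CPM.

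**Figure D5:**
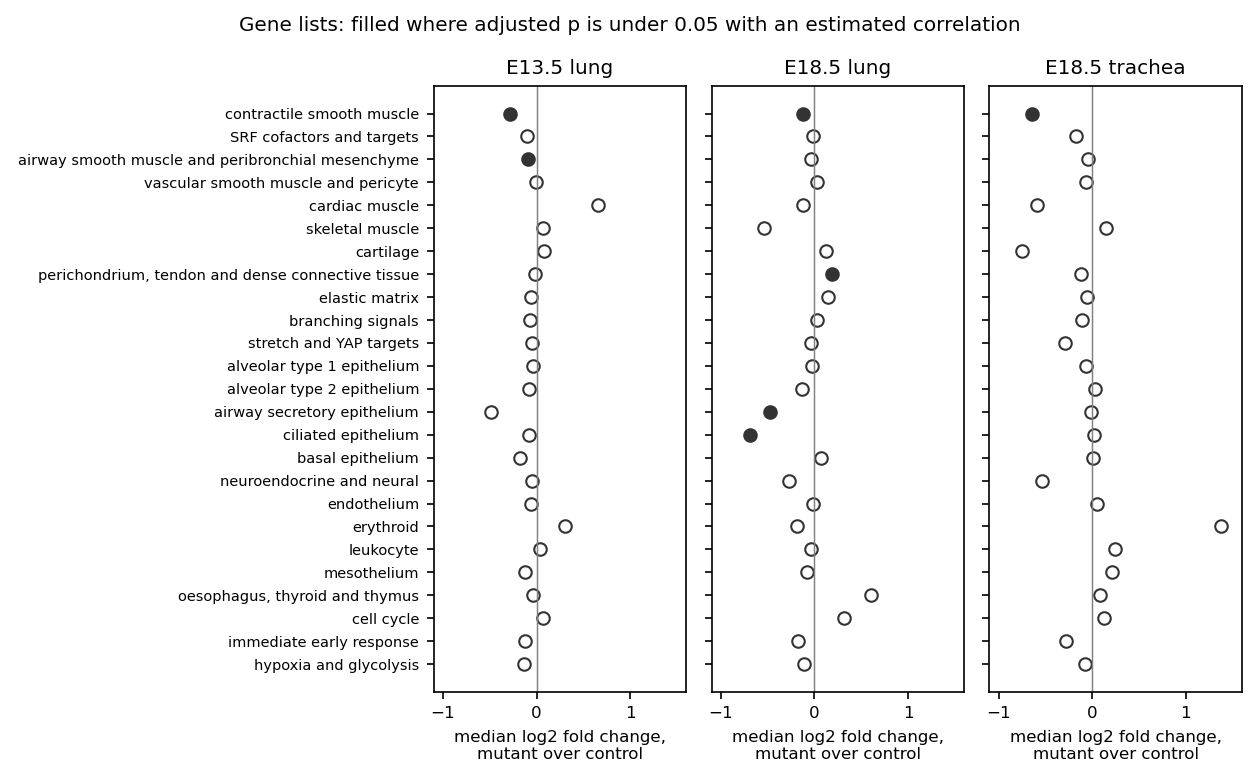
Median log2 fold change, mutant over control, of each of the 25 gene lists in E13.5 lung, E18.5 lung and E18.5 trachea; filled points have an adjusted p under 0.05 with an estimated correlation. Contractile genes lie at -0.29, -0.12 and -0.64, and ciliated genes at -0.08, -0.69 and 0.01.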

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

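Chosen only after the result was seen were the test of cartilage genes in E18.5 lung and the fit of the trachea without control replicate 2 and mutant replicate 4. The use of E13.5 control replicate 4 to read the Gm1821 values was also chosen after those values were seen. The 12 single values that stood apart by Dixon's test are given with the range of their group; 104 groups were tested, and chance marks about 1 in 20 groups.

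In E13.5 controls, Acta2 was 279.8 CPM in replicate 3 against 336 to 355 CPM in the others. Among E13.5 mutants, Cnn1 was 14.3 CPM in replicate 5 against 4.32 to 6.82 CPM, and Myh11 was 94.0 CPM in the same library against 32.1 to 42.3 CPM. The contractile list score of that library was 0.0321, against -0.474 to -0.254 in the other mutants and 0.0586 in the lowest control. That score did not stand apart by Dixon's test. Rpl29 was 70.5 CPM in E13.5 mutant replicate 1 against 123 to 135 CPM, and ribosomal RNA genes took 0.0949% of its counts against 0.0591% to 0.0688%. In E18.5 lung, Mmp23 was 9.37 CPM in control replicate 1 against 7.79 to 8.05 CPM, Acta2 was 96.7 CPM in mutant replicate 3 against 112 to 121 CPM, and the secretory score was -0.88 in mutant replicate 6 against -0.16 to 0.09. In the trachea, Cytl1 was 350.7 CPM in control replicate 3 against 290 to 294 CPM, Tymp was 23.2 CPM in mutant replicate 5 against 15.5 to 18.1 CPM, and ribosomal RNA took 3.32% in control replicate 1 against 1.03% to 1.22%.

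Mutant effects that differed between tissues were those of Myh11 (-1.61), Cytl1 (-1.5), Rgs2 (-1.07), Mylk (-0.86) and Lrrc23 (1.2), and the contractile (-0.599), cartilage (-0.96) and ciliated (0.78) lists. Effects that differed between stages were those of Ccdc150 (-1.6), Nupr1 (-1.47), Mns1 (-1.27), Lgr6 (1.26) and Acta2 (1.11).

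Gm1821 was 0.675 CPM in E13.5 control replicate 4 against 30.3 to 34.0 CPM in the other controls. A strain variant carried with the floxed allele would lower Gm1821 in every animal with 2 floxed alleles, yet control replicate 1, labelled with 2, was at 30.3 CPM. By the reading set beforehand, 30.3 CPM counted against a strain variant. That value is not decisive, because replicate 4, labelled with 1 floxed allele, was at the mutants' level, and the values would follow the floxed allele if the labels of these 2 controls were exchanged, which counts cannot check. A loss of Myocd function is likewise left open by the 0.675 CPM of control replicate 4, a single library. The reading set beforehand asked whether control replicate 1 lay inside the range of the other controls. It did, but that range began at the 0.675 CPM of replicate 4, so this reading could not decide. Reads shared with a similar ubiquitin gene linked to Myocd remain possible: the most similar expressed gene, Ubb, with 98.5% identity over 685 bases, lies 2.62 Mb from Myocd, so a Ubb variant near the floxed allele could move reads to or from Gm1821.

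Ciliated and secretory genes fell in E18.5 mutant lung. Xist, high in females, was high in control replicates 2 and 4 and in mutant replicates 1, 2 and 4. Each genotype thus held females and males in equal shares. Xist as a covariate could therefore hardly move the ciliated median, which was -0.69 with it. This balance, rather than the covariate, argues against embryo sex for the ciliated and secretory genes. Fewer airway epithelial cells could lower both groups alike: the ciliated score changed by -0.19 relative to the secretory score (exact permutation p 0.31, 210 splits, two-sided), which leaves a shared loss of cells and a loss of differentiation open. That value was -0.11 without control replicate 4, -0.1 without mutant replicate 4 and -0.28 without mutant replicate 6, with exact permutation p of 0.56, 0.492 and 0.0873. Basal genes did not fall with them (median 0.07, 7 of 9 above 0, camera adjusted p 0.572). However, 4 of the 9 were under 5 CPM, and whether this list follows basal cells in the lung was not tested. A loss that includes basal cells therefore stays open. Less proximal bronchus in the mutant lobes also stays open: the cartilage median was 0.13, but 4 of 19 cartilage genes were at 5 CPM or more in control lung and 10 times higher in control trachea, too few to show a loss of bronchus.

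Tracheal libraries varied more within genotype, with a biological coefficient of variation of 0.370 against 0.184 in E18.5 lung. Lung counts thinned to the tracheal totals gave 0.171. This coefficient leaves out counting noise, so thinning could hardly raise it, and the test does not exclude sequencing depth. Control replicate 2 and mutant replicate 4 may carry part of the tracheal variation: without them the value was 0.282, near the midpoint of 0.277, and 0.262 to 0.320 with 1 more library out. Tissue of neighbouring organs was left open. In trachea, 3316 of 16499 genes that followed none of the neighbouring-organ scores had a median coefficient of variation of 0.177 against 0.207 for all genes. The same genes were also lower in lung, at 0.119 against 0.134, so the choice of genes by itself lowered the value and the test decided nothing.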

How the results depend on the processing

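The covariates for ribosomal RNA and transcript length slope, the fits without pairs of libraries, and all alternatives for lists other than the contractile lists and the tracheal cartilage list were chosen after seeing the data. The 34 genes of E13.5 lung were 82 with DESeq2 (28.0% higher in mutants, against 8.82%), 0 with the replicate block, 18 against 1.2-fold, 2 without control replicates 1 and 4, and 17 to 56 with 1 library left out. At E13.5 replicates share only a number, with correlations of -0.377 to 0.0169, so the block is not a weaker effect. The 102 of E18.5 lung were 264 with DESeq2, 192 with no filter, 12 against 1.2-fold, 5 with the ribosomal RNA covariate, which lay apart between genotypes, 54 with the length slope, and 26 to 205 with 1 library left out. The 13 of the trachea were 89 with DESeq2, 25 with limma-voom, 22 with no filter, 28 with the block, 6 against 1.2-fold, 3 with ribosomal RNA, 7 with length slope, 45 without control replicate 2 and mutant replicate 4, 156 in 1 fit of all 30 libraries, and 3 to 16 with 1 library left out. The 5 of the tissue difference were 64 with DESeq2, 12 without tracheal control replicate 2 and mutant replicate 4, and 2 to 9 with 1 library left out; the block ended the call of Lrrc23 (adjusted p 0.0662). The 5 of the stage difference were 41 with DESeq2, 1 with the block (Mns1) and 3 to 19 with 1 library left out. Genes called in at least 2 comparisons were 22 with DESeq2, against 5. DESeq2 made more false calls in simulation. Among named genes and lists, the block changed no call in E18.5 lung beyond those given with that comparison; over all genes it kept 52 of the 102. With 1 library left out, contractile medians were -0.35 to -0.21 in E13.5 lung, -0.14 to -0.07 in E18.5 lung and -0.81 to -0.51 in the trachea, and the cartilage median -1.02 to -0.58. The E18.5 lung contractile median was -0.0475 with ribosomal RNA (adjusted p 0.0537). The tracheal cartilage median of -0.75 had adjusted p 0.186 with an estimated correlation and 0.119 with fry. Directions turned for alveolar type 1 genes at E13.5 without control replicate 1 (0.0056) or mutant replicate 3 (0.0186; lowest -0.134 without mutant replicate 1), alveolar type 2 without control replicates 1 and 4 (0.0035), and the immediate early list in E18.5 lung with ribosomal RNA (0.32). In the trachea they turned for the airway smooth muscle list with ribosomal RNA (0.13), length slope (0.103), without control replicate 3 (0.0077) or 4 (0.0119), without mutant replicate 4 (0.12; lowest -0.119 without mutant replicate 3), or without it and control replicate 2 (0.0619), for skeletal muscle with the block (-1.1), for perichondrium with ribosomal RNA (0.0649) or length slope (0.0346), and for ciliated genes without control replicate 2 and mutant replicate 4 (-0.17). The cause was not tested. Over 196 results for named genes, 3462 of 4026 settings gave the same label, 304 were weaker, 10 stronger, 250 moved and 0 reversed; for the 9 difference genes 194 of 230 were the same and 36 weaker; for 71 other list results 1076 of 1325 were the same, 91 weaker, 60 stronger, 84 moved and 14 reversed. Lung and trachea libraries of the same number lay on the same side of 10 CPM of Xist in 10 of 10 pairs. Each of the 10 mutant and control libraries correlated best with its own number, a hint of shared embryos. Without genes of the sex chromosomes, 4 of 4 controls and 5 of 6 mutants still correlated best with their own number. By the limit of 0.1, 3 of 4 controls and 2 of 6 mutants passed without these genes.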

Other observations

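Alternatives for the lists of this part were chosen after the data were seen. Cell cycle genes had a median log2 fold change of 0.32 in E18.5 mutant lung, all 22 above 0, with 0 past the edgeR test and 13 higher adjusted over the list alone. The list passed camera at the preset correlation (adjusted p 9.22e-16) but not with an estimated correlation (adjusted p 0.17). Top2a, a topoisomerase of dividing cells, was 177 ± 37 against 213 ± 25.7 CPM, and Mki67, a proliferation marker, 192 ± 31.2 against 217 ± 21 CPM. In E13.5 lung and trachea the cell cycle list had medians of 0.07 (adjusted p = 0.0614 with an estimated correlation) and 0.12 (adjusted p = 0.587 with an estimated correlation). Red cell genes had medians of 0.31, -0.18 and 1.37 in E13.5 lung, E18.5 lung and trachea, with estimated-correlation adjusted p of 0.273, 0.151 and 0.301. Slc4a1, the anion exchanger of red cells, fell from 21.5 ± 5.85 to 11.3 ± 2.33 CPM in E18.5 lung, a log2 fold change of -0.93 (SE 0.173, adjusted p 0.0167) by edgeR, and it lost its call without control replicate 3 or 4 or mutant replicate 4 or 6 (-0.9 to -0.77). The beta globin gene Hbb-bs was 289 ± 71.9 against 787 ± 587 CPM in the trachea.

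The cardiac list had medians of 0.66, -0.12 and -0.59, with 4 of 13 higher at E13.5 adjusted over the list alone (adjusted p = 0.133 with an estimated correlation), and the skeletal list 0.07, -0.54 (adjusted p = 0.392 with an estimated correlation) and 0.15, the last -1.1 with the replicate block. In tracheal controls the skeletal actin gene Acta1 ran from 7.66 to 1201 CPM and the thyroglobulin gene Tg from 3.57 to 592 CPM; in mutants they ran from 5.61 to 1432 CPM and 15.4 to 522 CPM. Neuroendocrine and neural genes had medians of -0.05 in E13.5 lung, -0.27 in E18.5 lung and -0.54 in the trachea, the last with adjusted p = 0.344 with an estimated correlation. At E13.5, 1 of 18 fell by the edgeR test, and the list had adjusted p = 0.538 with an estimated correlation. S100b, of glia and cartilage, was 41.7 ± 0.659 against 23.1 ± 5.12 CPM in the trachea and did not pass (adjusted p 0.0733 by edgeR). Endothelium had medians of -0.06, -0.02 and 0.05, the last with a mean and test of opposite sign. Leukocytes had 0.03, -0.04 and 0.24, the first with a test of opposite sign, and none passed in the main fits. With the replicate block, the leukocyte and mesothelium lists of E18.5 lung passed camera at the preset correlation, as given above. Mesothelium had -0.12 (adjusted p = 0.361 with an estimated correlation), -0.08 and 0.21. Genes of oesophagus, thyroid and thymus had -0.04, 0.61 and 0.09. The immediate early response had -0.13, -0.18 and -0.28 (adjusted p 0.133 at E13.5 and 0.301 in the trachea with an estimated correlation), and hypoxia and glycolysis -0.13, -0.12 and -0.08 (0.133 and 0.392 in the lungs). The E18.5 lung immediate early median was 0.32 with ribosomal RNA as a covariate.

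Libraries were also split in other ways to see how often labels drawn at random give as many genes. In E13.5 lung 2 of 100 splits gave at least 34 genes, and the highest other split gave 1367; that split set control replicates 1 and 3 and mutant replicates 2, 4 and 5, the libraries with a transcript length slope above 0, against the rest and points to a structure of the samples. In E18.5 lung 2 of 100 splits gave at least 102 genes, the highest other 383, which set control replicates 1 and 3 and mutant replicates 1 and 3, those with the highest length slopes, against the rest; among 10 splits that part all 4 pairs the highest other was 0. In the trachea 1 of 100 splits gave at least 13 genes, the highest other 1; for the tissue difference it was 1 of 60, the highest other 2, and for the stage difference 2 of 60, the highest other 7. A contractile median at least as far from 0 came from 6 of 100 splits at E13.5 (highest other -0.34), so chance was not excluded there for the median, from 4 of 100 in E18.5 lung (-0.14) and from 1 of 100 in the trachea (0.55).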
